A study of Anguilla anguilla with 21 samples.

How the data were processed

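Gene expression was measured in spleens of elvers of the European eel (Anguilla anguilla) fed LPSp, a preparation of bacterial lipopolysaccharide, at 0, 20 or 40 µg per kg body weight per day for 70 days. Per the labels, each sample was RNA from a pool of 3 spleens, each diet had 4 replicate tanks, and each pool was hybridised to its own 1-colour (Cy3) Agilent array. The groups are called control, LPSp_20 and LPSp_40, with 7 arrays each. The labels give neither the tank of a pool nor any pairing of replicate numbers between diets.

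The deposited files per array hold linear fluorescence intensity, and per the file headers this intensity was background-subtracted and detrended by Agilent Feature Extraction 10.7.3.1, with no scaling between arrays. The deposited series table holds log2 values for 48221 probes. A check on the files showed these log2 values to be the quantile-normalized log2 intensity minus the mean of the 7 control arrays, with a median absolute difference of 0.000373. The filter that chose its probes is not stated. The deposited flags of each spot (other than the intensities) mark whether it was well above background, saturated or an outlier.

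Each array carries 61657 non-control spots for 61377 probes. Control spots and outlier-marked spots were dropped, replicate spots of a probe were averaged, and log2 of the processed intensity was scaled by subtracting each array's 75th percentile. A probe was tested if it was well above background on at least 7 of the 21 arrays, counted without regard to diet, which kept 45984 probes. The share of spots well above background ran from 61.9% to 75.03% per array, 0 spots were saturated, and the number of arrays limits the precision.

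The files name genes by identifiers of an eel transcript database whose text is shortened to 16 characters. Of 11841 gene identifiers with a tested probe, 2927 showed some text and 2602 a usable name, of which 2027 were shortened. Names are therefore printed as the visible text followed by the database number, and no shortened name was completed. The reference symbols supplied matched 0 of the identifiers and was not used here.

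All comparisons came from 1 linear model over the 21 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided moderated test), adjusted by Benjamini and Hochberg over the tested probes and called at an adjusted p under 0.05. The 3 pairwise comparisons, an F test of any difference among diets and a linear trend on dose were made. Standard errors beside log2 changes are those of this model. Files were read with the packages data.table (version 1.17.8) and jsonlite (version 2.0.0), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

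Gene lists were tested with 1 probe per gene, the probe with the highest mean, by limma's camera with a preset correlation of 0.01, adjusted over the 28 tested lists of a comparison. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance in 1 direction, were run beside it. The lists were LPS sensing and TLR-NFkB signalling, pro-inflammatory cytokines and chemokines, anti-inflammatory and regulatory, complement, acute phase and antimicrobial, lectins and scavenger receptors, MHC and antigen presentation, interferon and antiviral, B cell and immunoglobulin, T and NK cell, macrophage and granulocyte, erythroid, liver, muscle, intestine and epithelium, proliferation, ribosomal proteins, translation factors, oxidative phosphorylation, glycolysis and carbohydrate metabolism, lipid metabolism, heat shock and ER chaperones, oxidative stress and detoxification, immediate early and handling stress, apoptosis, lysosome and autophagy, proteasome and ubiquitin, and extracellular matrix and stroma. A thrombocyte and vascular list (1 gene found) and an exocrine pancreas list (2 genes found) fell under the minimum of 5 genes and were not tested. Membership rests on the visible text, so the signal transduce entries of the interferon list, for example, are listed by their shortened name alone.

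The main model, filter, threshold, list contents, rule for named genes and most alternatives were fixed before the data were examined. The phrases of the lists were matched to the shortened names once the annotation had been read, and 1 phrase was taken out of the macrophage and granulocyte list after list results had been seen, to follow the fixed contents. The rule for named genes took, per comparison, the 12 named genes with the largest called change in each direction on the brightest probe, filled to 6 by smallest p where fewer passed, plus up to 4 members of each list discussed. Gene families sharing a visible name were chosen after their values had been seen. The mean of each list per array (each member minus its control mean) was compared by two-sided exact permutation tests over all splits of the arrays into the 2 diets, a test added after the list results had been seen.

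Slide and row of each array on its slide were read from the identities of the deposited files. All control arrays lay in row 1, all LPSp_20 arrays in row 2, and LPSp_40 had 5 arrays in row 1 and 2 in row 2, over 3 slides. Slide 1 held control replicates 1 and 2 and replicates 1, 2 and 3 of each LPSp diet. Slide 2 held control replicates 3 and 4 and replicates 4, 5 and 6 of each LPSp diet. Slide 3 held control replicates 5, 6 and 7 and only replicate 7 of each LPSp diet. For named genes not well above background on all arrays, the difference was also computed with each value raised to the lowest well-above-background value of its array, called the background floor, a step added after results had been seen, as were differences in list mean without single arrays. Principal components of the tested probes were compared with diet, slide and row by permutation tests with 100000 permutations (12 tests).

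Alternatives were quantile and median scaling, normexp background correction with an offset of 50, the deposited table, no filter or a filter on all 21 arrays, 1 probe per gene, slide as a fixed or random block, row as a term, fits within a slide or row, replicate number as a block, arrayWeights, trended and robust eBayes, other thresholds, the 2 compared groups alone and each array left out in turn. Leaving out 2 or 3 arrays that stood apart (LPSp_20 replicates 3 and 7, then also control replicate 6) was chosen after seeing the data.

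The procedure was tested on simulated data of independent normal noise, with the mean and residual SD of each probe. Correlation between genes, on which list tests depend, was thus absent, and the list rates below do not carry over to the real arrays. A planted log2 change of 1 was called for 64.2% to 65.7% of probes in the 3 comparisons, a change of 0.5 for 25.4% to 29.9% and a change of 2 for 81.8% to 83.3%, with 3 to 7 false calls. A list raised by 0.5 in LPSp_40 alone was called in 100 of 100 draws in both comparisons of that diet. Another list was called in 1, 4 and 2 of these draws in the 3 comparisons, and these rates over draws replaced a single draw after that draw had called a list by chance. In 57 of 100 splits of the real arrays, the real one included, at least 5 lists were called for LPSp_20 against control. For each count, 100 splits of the arrays, the real one included, were drawn with a fixed seed.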

Results

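Spleen transcripts were measured on 21 arrays, 7 each for eels fed the control diet, LPSp_20 and LPSp_40, and their number limits the precision. The LPSp_20 and LPSp_40 diets carried LPSp, a preparation of lipopolysaccharide (LPS, a component of the outer membrane of Gram-negative bacteria), coated onto the pellets. Each array held RNA of 1 pool of 3 spleens after 70 days of feeding at 0, 20 or 40 µg per kg body weight per day. Each diet had 4 tanks for its 7 pools, and the tank of each pool is not given. All tests, the exact permutation tests included, treat pools as independent, which pools of 1 tank may not be. The p-values therefore measure the spread between pools and not between tanks. Between 61.9% (LPSp_40 replicate 4) and 75.03% (LPSp_20 replicate 3) of the spots of an array were well above background, and 45984 of 61377 probes were tested. Reported values are log2 intensity relative to the 75th percentile of each array, and ± gives the SE of the model unless SD is stated. Gene names are the visible text of the files, most of it shortened to 16 characters, with a database number.

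The first question was whether the higher dose changed expression in the spleen. Interferon and antiviral genes rose in LPSp_40 against control. The mean of the 22 genes of this list was 1.31 ± 0.64 on the log2 scale in LPSp_40 (SD, n = 7) and 0.00 ± 0.25 in control (SD, n = 7). All 7 LPSp_40 arrays, at 0.38 to 2.12, lay above the highest control array at 0.32. Among named genes that passed, the largest change was in vhsv-induced pro 05195, named for induction by VHSV, the viral haemorrhagic septicaemia virus of fish, at 14.7-fold (log2 3.87 ± 0.58, SE, n = 7 per diet, limma adjusted p = 0.00154).

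Of the 22 interferon and antiviral genes, 13 rose and 9 did not pass over all tested probes. Adjusted over the list alone, 16 rose, and 20 were higher in sign. Camera gave an adjusted p = 6.76e-22 for the list and adjusted p = 0.0434 with an estimated correlation, the highest of 9 alternatives (lowest 8.24e-23). Fry gave 0.000403. An exact permutation test of the list mean gave p = 0.000583 (n = 7 per diet), the smallest that 3432 splits can give, and 0.0163 adjusted over 28 lists. The members interferon induc 02230 (2.58 ± 0.37, adjusted p = 0.00149), interferon-induc 02241 (2.19 ± 0.34, adjusted p = 0.00196), interferon-induc 02248 (1.87 ± 0.30, adjusted p = 0.00233) and interferon-induc 02244 (1.69 ± 0.28, adjusted p = 0.00268) had the smallest p. Members mx protein 02891 (log2 -0.17, adjusted p = 0.917) and mx2 protein 02892 (log2 -0.30, adjusted p = 0.883), of a family of interferon-induced GTPases, did not pass.

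**Figure D1:**
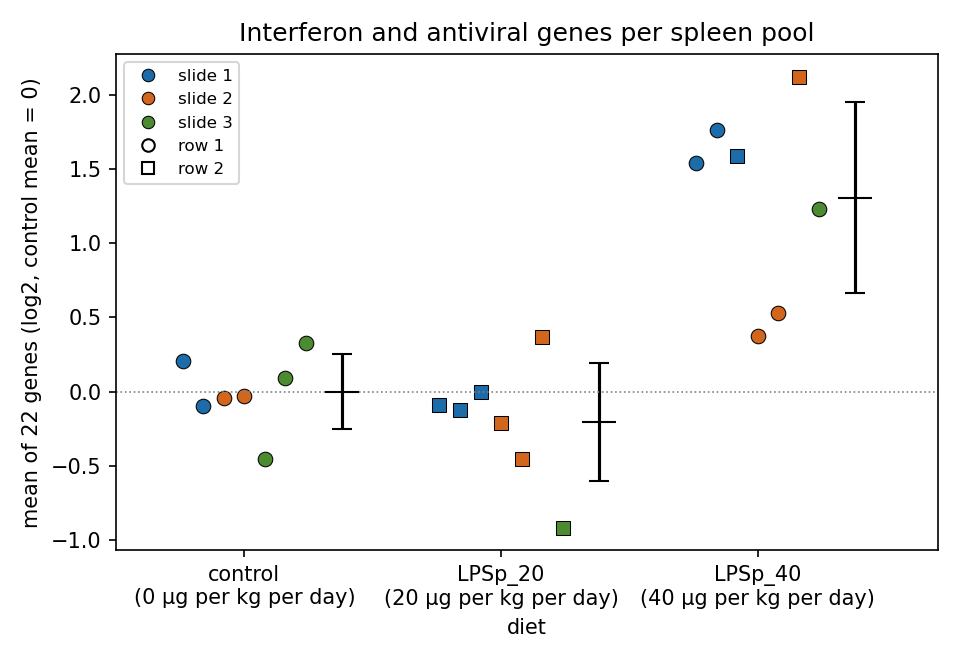
The mean log2 expression of the 22 interferon and antiviral genes relative to control is plotted per array by diet, with colour for the slide, shape for the row, and bars for mean ± SD of 7 arrays. The LPSp_40 arrays lie between 0.38 and 2.12, above the highest control array at 0.32 and the highest LPSp_20 array at 0.37.

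Other large increases in LPSp_40 against control were in ubiquitin-like p 05061 (3.13 ± 0.52, adjusted p = 0.00271), 05067 (3.00 ± 0.54, adjusted p = 0.00458) and 05072 (2.32 ± 0.40, adjusted p = 0.00359). The gene hect domain and 01993, whose domain is known from ubiquitin ligases, rose by 3.02 ± 0.43 (adjusted p = 0.00149). Further increases were in fish virus induc 01628 (2.92 ± 0.56, adjusted p = 0.00767, well above background on 1 of 7 control arrays, 2.53 with values raised to the background floor) and receptor transpo 03925 (2.43 ± 0.43, adjusted p = 0.00380). Nicotinamide pho 03079 rose by 2.33 ± 0.44 (adjusted p = 0.00656, well above background on 4 of 7 control arrays, 1.90 at the floor) and interferon regul 02233 by 2.34 ± 0.41 (adjusted p = 0.00399, well above background on 4 of 7 control arrays, 2.29 at the floor). The interferon-induc entries 02238 (2.79 ± 0.68, adjusted p = 0.0394) and 02249 (2.65 ± 0.61, adjusted p = 0.0270) also rose. The 2 other probes of 02238 had the same sign and did not pass, while those of 02249 passed. In families chosen after their values had been seen, 8 of 12 fish virus induc identifiers rose (median log2 1.36) and 6 of 10 interferon-induc identifiers rose. Named genes that fell included histone 02059 (-0.57 ± 0.13, adjusted p = 0.0264) and histone h5a 02093 (-0.51 ± 0.13, adjusted p = 0.0449). Asparagine-linke 00334 (-0.45 ± 0.10, adjusted p = 0.0181) and plectin isoform 03496, of a linker of the cytoskeleton (-0.39 ± 0.08, adjusted p = 0.0174), fell too. The 2 other probes of histone h5a 02093 and of plectin isoform 03496 had the same sign and did not pass. The deacetylase sirtuin 2 04315 (-0.45, adjusted p = 0.0543, with its other 2 probes of opposite sign) and plectin isoform 03494 (-0.36, adjusted p = 0.0622) did not pass.

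**Figure D2:**
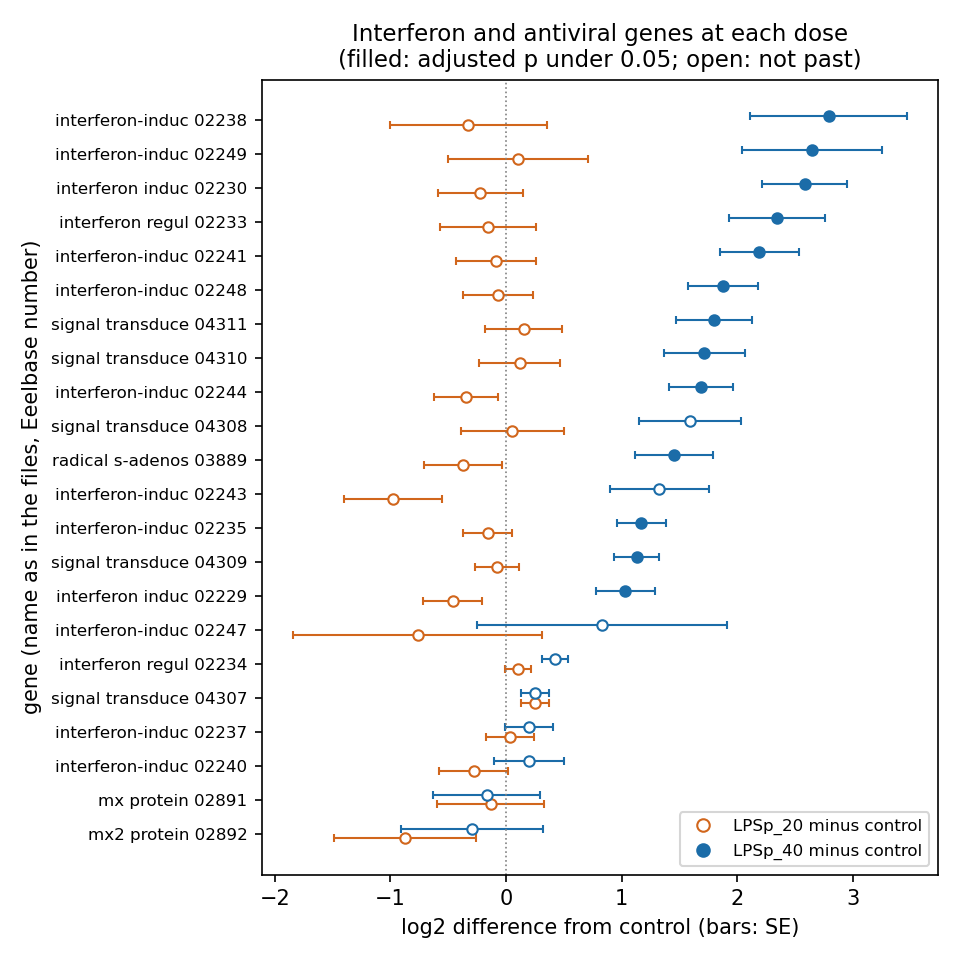
The log2 change of each of the 22 interferon and antiviral genes against control is plotted for LPSp_20 and LPSp_40 with its SE, and filled markers have an adjusted p under 0.05. The LPSp_40 changes pass for 13 of the 22 genes and the LPSp_20 changes for 0 (limma).

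Markers of intestine and epithelium were lower in LPSp_40 than in control as a list. All 12 were lower in sign with a median log2 of -0.63, 0 passed over all probes and 2 passed adjusted over the list alone. The list had adjusted p = 0.000334 and adjusted p = 0.106 with an estimated correlation. The exact permutation test of the list mean gave p = 0.00583, or 0.0816 adjusted over 28 lists, and did not pass. Among its members, muc2 protein 02867, a gel-forming mucin of goblet cells, had a log2 of -4.32 ± 1.16 (adjusted p = 0.0724). It was well above background on 4 of 7 LPSp_40 arrays, and with values raised to the background floor its log2 was -3.59, or -2.92 without control replicate 6. Claudin 4 00908, a tight junction protein, had -2.81 ± 0.95 (adjusted p = 0.201). It was well above background on 2 of 7 LPSp_40 and 6 of 7 control arrays, and at the floor its log2 was -1.81, or -0.997 without control replicate 6. Control replicate 6 stood above the other control arrays with a list mean of 1.69, and without it the LPSp_40 list kept its call (adjusted p = 0.00469). With only probes well above background on all 21 arrays, the list had adjusted p = 0.126, the highest of 9 alternatives (lowest 0.000181). Mucin subtype tr 02871, not well above background on any LPSp_40 array, was at least 1.63-fold higher in control, on 3 of 7 arrays, than its background floor in LPSp_40 (adjusted p = 0.441), and at least 1.12-fold without control replicate 6.

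The other lists called in LPSp_40 against control each lost the call with an estimated correlation. B cell and immunoglobulin genes were lower (adjusted p = 0.00701, adjusted p = 0.768 with an estimated correlation). Of the 17 genes, 13 were lower in sign, the median was -0.31, and 0 passed over all probes or adjusted over the list alone. The 4 members of smallest p were immunoglobulin entries at -0.32 to -0.39. Extracellular matrix and stroma genes were lower in 8 of 8, with a median of -0.24 (adjusted p = 0.00574, adjusted p = 0.510 with an estimated correlation). Of these 0 passed over all probes and 1 adjusted over the list alone. Examples were collagen type i 00980 (-0.47, adjusted p = 0.455) and sparc precursor 04411, a matrix glycoprotein (-0.29, adjusted p = 0.362). Proteasome and ubiquitin genes were higher, with a median of 0.08 and 57 of 82 higher in sign (adjusted p = 0.0405, adjusted p = 0.768 with an estimated correlation). Of the 82, 1 rose both over all probes and adjusted over the list alone, ubiquitin-conjug 05024 (0.97 ± 0.17, adjusted p = 0.00354). The exact permutation tests of the list means did not pass for B cell genes (adjusted p = 0.318), extracellular matrix (0.318) or proteasome and ubiquitin (0.472). The difference in list mean went from -0.24 to -0.16 without LPSp_40 replicate 1 for extracellular matrix, and for the proteasome list from 0.04 to 0.07 without LPSp_40 replicate 2 and to 0.03 without replicate 6. The proteasome call was lost with slide as a block (adjusted p = 0.264), with a row term (0.619), with quantile scaling (0.119), with a replicate block (0.0503) and with the filter on all 21 arrays (0.0550), in a range of 0.00866 to 0.768 over 9 alternatives. It was also lost without control replicates 1 (0.0580) or 5 (0.0888) or LPSp_40 replicates 1 (0.0614), 3 (0.120) or 6 (0.249).

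Over all probes, 696 passed in LPSp_40 against control, 566 higher and 130 lower, with 472 changed over 2-fold. They covered 257 gene identifiers, and 5180 probes had an unadjusted p under 0.05. The count was 302 with a row term, 241 with slide and row terms, and 4 among the arrays of row 1 alone (5 LPSp_40 and 7 control arrays, 1 higher and 3 lower). It was 15 within slide 1, 0 within slide 2 (limma, 6962 at an unadjusted p under 0.05) and 438 without LPSp_40 replicate 6. On the brightest probe of each gene 48 named genes were higher and 4 lower. Of the 20 of these that the rule for named genes took, 13 passed with a row term and 15 in every fit with an array left out. The others reached at most an adjusted p of 0.0997 for interferon-induc 02238 (without control replicate 5, passing in 8 of 21 such fits) and 0.0734 for 02249 (without control replicate 1, passing in 14). Without LPSp_40 replicate 6 it was 0.0722 for histone 02059 (passing in 14), 0.119 for histone h5a 02093 (passing in 4) and 0.0529 for asparagine-linke 00334 (passing in 19, and 0.0504 without control replicate 1), in a range of 0.000375 to 0.161 over the alternatives for the 20 genes.

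The next question was whether the lower dose changed expression. In LPSp_20 against control, the interferon and antiviral genes did not pass, and 10 named genes passed, 7 higher and 3 lower. The largest increase among these 10 was in ubiquitin-conjug 05024, at 2.35-fold (log2 1.23 ± 0.17, SE, n = 7 per diet, limma adjusted p = 0.00211), with all 7 LPSp_20 arrays above all controls. Of the glutamine synthe entries 3 of 4 rose, 01788 (0.92 ± 0.18, adjusted p = 0.0255), 01787 (0.91 ± 0.19, adjusted p = 0.0316) and 01786 (0.88 ± 0.18, adjusted p = 0.0311).

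Also higher in LPSp_20 were b cell rag assoc 00384 (0.97 ± 0.20, adjusted p = 0.0278), uncoupling prote 05108 (0.80 ± 0.13, adjusted p = 0.00679) and deoxyribonucleas 01266 (0.76 ± 0.16, adjusted p = 0.0330). The genes zinc cchc domain 05268 (-0.65 ± 0.14, adjusted p = 0.0404), histone h5a 02093, of the linker histones of nucleated red cells (-0.60 ± 0.13, adjusted p = 0.0327) and mrg-binding protein 02857 (-0.54 ± 0.10, adjusted p = 0.0175) fell. Next by p, the genes multiple myeloma 02879 (-0.45, adjusted p = 0.0711), inhibitor of dna 02209 (-0.48, adjusted p = 0.0764) and structure specif 04476 (-0.35, adjusted p = 0.108) did not pass. Control replicate 1 lay far below the other controls for glutamine synthe 01788, and control replicate 7 far above them for b cell rag assoc 00384. Of these 10 genes, ubiquitin-conjug 05024, uncoupling prote 05108 and mrg-binding protein 02857 passed in every fit with an array left out. Of the 2 other probes of each, 1 passed for ubiquitin-conjug 05024 and 0 for the other genes (limma), all with the same sign. The 2 other probes of histone h5a 02093 and of deoxyribonucleas 01266 had the same sign and did not pass either. Without LPSp_20 replicate 3 the adjusted p was 0.0724 for b cell rag assoc 00384 and 0.0656, 0.0774 and 0.0753 for the 3 glutamine synthe entries. It was 0.0812 for deoxyribonucleas 01266 and 0.0982 for zinc cchc domain 05268 without LPSp_20 replicate 6, and 0.0831 for histone h5a 02093 without control replicate 6. These 7 genes passed in 6 to 17 of the 21 such fits. With a row term 0 of the 10 passed (limma), and over their alternatives the adjusted p ran from 0.000954 to 0.730.

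Complement genes were higher as a list in LPSp_20, with 10 of 11 higher in sign and a median of 0.25 (adjusted p = 0.0436, adjusted p = 0.337 with an estimated correlation). Of the 11, 0 passed over all probes and 1 adjusted over the list alone. The list mean differed by 0.41 (exact permutation p = 0.00117, 0.0326 adjusted over 28 lists), or 0.25 without LPSp_20 replicate 7, which lay at 1.38 with the other 6 arrays at 0.14 to 0.38. In the same replicate 7 the liver list mean was 2.56, against -0.14 to 0.11 in the other LPSp_20 arrays. The members were led by complement recep 00999 (0.65 ± 0.19, adjusted p = 0.149) and complement c3-h1 00989, of the central component of the cascade (1.44 ± 0.73, adjusted p = 0.457). The latter lay 6.44 above the median of the other arrays in replicate 7, and its log2 change was 0.58 in the lowest of the 21 fits with an array left out. Complement compo 00991 had a log2 of 0.18 (adjusted p = 0.515), which turned to -0.24 with a row term. The list call was lost with quantile scaling (adjusted p = 0.111), with a row term (0.972), with all probes of a gene averaged (0.116), and with the filter on all 21 arrays (0.0580), in a range of 0.0195 to 0.972 over 9 alternatives. It was also lost without control replicates 1 (0.0546), 2 (0.0693), 3 (0.0643) or 6 (0.0619), LPSp_20 replicates 4 (0.0675), 5 (0.0501) or 7 (0.0508) or LPSp_40 replicates 1 (0.0516) or 7 (0.0511).

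B cell and immunoglobulin genes were lower in LPSp_20 as a list, with 16 of 17 lower in sign and a median of -0.33 (adjusted p = 2.46e-05, adjusted p = 0.75 with an estimated correlation). Of the 17, 0 passed over all probes or adjusted over the list alone, and the immunoglobulin heavy c entries had -0.39 to -0.46. LPSp_20 replicate 7 had a B cell list mean of -1.03, and without it the difference in list mean from control went from -0.26 to -0.13, with the list still called (adjusted p = 0.00388). Intestine and epithelium markers were lower, with 9 of 12 lower in sign and a median of -0.66 (adjusted p = 0.0384, adjusted p = 0.595 with an estimated correlation). Of the 12, 0 passed over all probes and 2 were lower adjusted over the list alone. Among its members were villin 1 05197, an actin-bundling protein of microvilli (-0.92 ± 0.31, adjusted p = 0.222, well above background on 2 of 7 LPSp_20 arrays, -0.75 at the floor), and muc2 protein 02867 (-3.43 ± 1.16, adjusted p = 0.223, on 5 of 7, -3.09 at the floor and -2.42 without control replicate 6). Another was anterior gradien 00297 (-2.01, adjusted p = 0.396, well above background on 1 of 7 LPSp_20 arrays, -0.94 at the floor and -0.496 without control replicate 6), which turned to 0.039 with a row term. The exact permutation tests of the list means did not pass for B cell genes (adjusted p = 0.651) or for intestine and epithelium (0.268). The intestine call was lost with quantile scaling (adjusted p = 0.0760), with slide as a block (0.159) and with a row term (0.972), and its direction turned with the filter on all 21 arrays (0.619), in a range of 0.0215 to 0.972 over 9 alternatives. Leaving out single arrays also ended it, namely control replicates 3 (0.0618) or 6 (0.141), LPSp_20 replicates 2 (0.0535), 4 (0.0825), 5 (0.0501) or 6 (0.0568) or LPSp_40 replicate 7 (0.0511).

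Ribosomal proteins were higher in LPSp_20 under the 75th percentile scaling, with 71 of 85 higher in sign and a median of 0.14 (adjusted p = 3.25e-06, adjusted p = 0.75 with an estimated correlation), and the direction turned with quantile scaling (adjusted p = 0.862, the highest of 9 alternatives, lowest 3.27e-10). Of the 85, 0 passed over all probes or adjusted over the list alone. Translation factors were higher in 45 of 49, with a median of 0.14 and 0 passing either way (adjusted p = 8.61e-05, adjusted p = 0.590 with an estimated correlation), and the call was lost with quantile scaling (adjusted p = 0.122, in a range of 3.36e-05 to 0.590 over 9 alternatives). The exact permutation tests of the list means did not pass for ribosomal proteins (adjusted p = 0.249) or translation factors (0.136). Examples were ribosomal protei 04085 (0.28, adjusted p = 0.118) and eukaryotic trans 01528 (0.24, adjusted p = 0.216). The interferon and antiviral list had a median of -0.14 with 15 of 22 lower in sign (adjusted p = 0.167, adjusted p = 0.892 with an estimated correlation), and 0 members passed over all probes or adjusted over the list alone. By the preset correlation it was called lower with a row term (adjusted p = 8.52e-06) and without control replicate 5 (0.0372) or LPSp_20 replicate 6 (0.0450).

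Over all probes, 226 passed in LPSp_20 against control, 87 higher and 139 lower, with 34 changed over 2-fold. They covered 111 gene identifiers, and 5467 probes had an unadjusted p under 0.05. All LPSp_20 arrays lay in row 2 of their slides and all controls in row 1. With a row term, 0 probes passed (limma, 3237 at an unadjusted p under 0.05), and 0 passed within slide 1 (3379) or slide 2 (4365). A slide held only part of the arrays of each diet, so fits within a slide have little power. The count was 113 without LPSp_20 replicate 3, 125 without replicate 4, 124 without replicate 6 and 471 without replicate 7 of that diet. The balance of directions turned as well, from 38.5% higher to 57.5% higher without replicate 7, 55.0% of 1051 with array weights and 54.4% of 619 at an unadjusted p under 0.01 with 1.5-fold. The count was 125, 127, 134, 144 and 125 without control replicates 1, 2, 4, 5 and 6. It was 83 with the 2 compared groups alone and 73 with the replicate number as a block.

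The third comparison, LPSp_40 against LPSp_20, asked whether the doses differed. Interferon and antiviral genes rose again, with 14 of 22 passing over all probes, 16 adjusted over the list alone and 21 higher in sign (median log2 1.59). The list had adjusted p = 1.50e-27 and adjusted p = 0.0156 with an estimated correlation, and the list mean of LPSp_20 was -0.20 ± 0.40 (SD, n = 7). An exact permutation test of the difference of 1.51 in list mean gave p = 0.000583 (n = 7 per diet), the smallest 3432 splits can give, and 0.0163 adjusted over 28 lists. Among named genes that passed, the largest change was again in vhsv-induced pro 05195, at 20.5-fold (log2 4.36 ± 0.58, SE, n = 7 per diet, limma adjusted p = 0.000364).

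Other large increases were in hect domain and 01993 (3.39 ± 0.43, adjusted p = 0.000310), ubiquitin-like p 05067 (3.26 ± 0.54, adjusted p = 0.00151), 05061 (3.16 ± 0.52, adjusted p = 0.00146) and 05072 (2.74 ± 0.40, adjusted p = 0.000686). Spastic ataxia o 04417 rose by 2.81 ± 0.42 (adjusted p = 0.000855). Interferon induc 02230 (2.81 ± 0.37, adjusted p = 0.000357), interferon regul 02233 (2.50 ± 0.41, adjusted p = 0.00153) and fish virus induc 01628 (2.77 ± 0.56, adjusted p = 0.0108) rose too. The latter was well above background on 3 of 7 LPSp_20 arrays and had 2.52 with values raised to the background floor. So did interferon-induc 02238 (3.11 ± 0.68, adjusted p = 0.0180) and 02249 (2.54 ± 0.61, adjusted p = 0.0375). Nuclear receptor 03245 rose by 2.41 ± 0.41 (adjusted p = 0.00217), with LPSp_20 replicate 7 far below the other LPSp_20 arrays. The named genes that were lower in LPSp_40 than in LPSp_20 were thyroid hormone recept (-0.69 ± 0.12, adjusted p = 0.00241) and ribosomal protei 04059 (-0.29 ± 0.07, adjusted p = 0.0406). The 1 other probe of the first and the 2 of the second had the same sign and did not pass. Neither gene passed against control, with -0.16 and -0.10 in LPSp_40 (limma adjusted p = 0.644 and 0.628) and 0.53 and 0.19 in LPSp_20 (0.0544 and 0.266). Next by p, the genes basic transcript 00405 (-0.35), eukaryotic trans 01491 (-0.31), 40s ribosomal pr 00041 (-0.32) and peroxiredoxin 5 03395 (-0.34) did not pass, at adjusted p from 0.0743 to 0.0878.

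Ribosomal proteins were lower in LPSp_40 than in LPSp_20 under the 75th percentile scaling, with 73 of 85 lower in sign and a median of -0.17 (adjusted p = 1.58e-10, adjusted p = 0.674 with an estimated correlation), and the direction turned with quantile scaling (adjusted p = 0.118, in a range of 3.17e-12 to 0.674 over 9 alternatives). Of the 85, 1 passed as lower over all probes and 3 adjusted over the list alone, and 60s acidic ribos 00049 went from -0.41 (adjusted p = 0.0957) to 0.013 with quantile scaling. Translation factors were lower in 37 of 49, with a median of -0.12 (adjusted p = 0.00370, adjusted p = 0.674 with an estimated correlation), with 0 passing over all probes and 2 adjusted over the list alone. They lost the call with quantile scaling (0.226) and with a row term (0.0857), in a range from 0.00125 to 0.674, and elongation facto 01405 went from -0.22 to 0.043 with quantile scaling. Macrophage and granulocyte markers were higher in 9 of 13, with a median of 0.18 (adjusted p = 0.0341, adjusted p = 0.674 with an estimated correlation). Of the 13, 0 passed over all probes and 1 adjusted over the list alone, and cd68 antigen 00711, a macrophage glycoprotein, had 0.68 ± 0.19 (adjusted p = 0.0951). Immediate early and handling stress genes were higher in 14 of 18, with a median of 0.23 and 0 passing either way (adjusted p = 0.0341, adjusted p = 0.674 with an estimated correlation). Among them was jun b proto-onco 02327 (0.35, adjusted p = 0.394).

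Among the lists called between the doses, the exact permutation test of the list mean passed for the interferon list alone and gave adjusted p = 0.212 to 0.648 for the other 7. Without LPSp_20 replicate 7 the difference in list mean went from -0.11 to -0.07 for oxidative phosphorylation, from -0.36 to -0.14 for lipid metabolism, from -0.20 to -0.09 for oxidative stress and from 0.16 to 0.09 for immediate early genes. Without LPSp_40 replicate 6 it was 0.06 in place of 0.16 for macrophage markers and 0.10 for immediate early genes, without LPSp_40 replicate 5 it was -0.07 in place of -0.11 for ribosomal proteins, and without LPSp_40 replicate 2 it was -0.31 for oxidative stress. Oxidative phosphorylation genes were lower in 75 of 96, with a median of -0.11 and 0 passing over all probes or adjusted over the list alone (adjusted p = 0.00209, adjusted p = 0.695 with an estimated correlation). Lipid metabolism genes were lower in 16 of 20, with a median of -0.45 and 0 passing either way (adjusted p = 0.0386, adjusted p = 0.674 with an estimated correlation). Among them fatty acid-bindi 01595 had -0.85 (adjusted p = 0.386). Oxidative stress and detoxification genes were lower in 30 of 40, with a median of -0.14 and 0 passing either way (adjusted p = 0.0341, adjusted p = 0.674 with an estimated correlation). Glutathione s-tr 01813 had -0.57 (adjusted p = 0.160). Lipid, oxidative stress and liver genes stood far above the other LPSp_20 arrays in replicate 7 of that diet (list means 1.30, 0.71 and 2.56). Without it the adjusted p was 0.424 for oxidative phosphorylation, 0.658 for lipid metabolism and 0.696 for oxidative stress. Leaving out single LPSp_40 arrays also ended calls, with 0.112 for oxidative phosphorylation without replicate 5 and 0.0505 to 0.110 for lipid metabolism without replicates 1, 3, 5, 6 or 7. For oxidative stress it was 0.0589 to 0.171 without replicates 4, 5, 6 or 7. With a row term these 3 lists had 0.656, 0.0530 and 0.0785, and over 9 alternatives they ranged from 0.000587 to 0.695, 0.0292 to 0.674 and 0.0292 to 0.696. With quantile scaling the calls were lost for oxidative phosphorylation (0.116), lipid metabolism, macrophage markers and immediate early genes (0.0510 each). The macrophage list was lost without LPSp_20 replicates 2 (0.114) or 3 (0.0889) or LPSp_40 replicates 3 (0.0600), 5 (0.0849) or 6 (0.204). The immediate early list was lost without LPSp_20 replicates 5 (0.0584) or 7 (0.0642) or LPSp_40 replicates 5 (0.0849) or 6 (0.161).

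Over all probes, 617 passed in LPSp_40 against LPSp_20, 555 higher and 62 lower, with 449 changed over 2-fold, and 5416 had an unadjusted p under 0.05. The count was 249 among the arrays of row 2 alone (2 LPSp_40 and 7 LPSp_20 arrays), 192 within slide 1 and 0 within slide 2 (limma, 3926 at an unadjusted p under 0.05). It was 395 with the 2 compared groups alone. On the brightest probe of each gene 41 named genes were higher and 2 lower. Of the 17 of these that the rule for named genes took, 14 passed in every fit with an array left out. Interferon-induc 02238 (adjusted p = 0.0526) and 02249 (0.0980) did not pass without LPSp_40 replicate 1 (passing in 20 and 12 of 21 such fits), nor ribosomal protei 04059 (0.108) without LPSp_20 replicate 5 (passing in 6). With a row term 13 of the 17 passed, and interferon-induc 02238 (adjusted p = 0.120) and 02249 (0.228), thyroid hormone recept (0.0934) and ribosomal protei 04059 (0.216) did not. Over the alternatives for the 17 genes the adjusted p ran from 0.000144 to 0.967, the highest for ribosomal protei 04059 with quantile scaling.

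Across the 3 diets, 917 probes passed the F test of any difference and 368 the linear trend on dose, 293 with a positive and 75 with a negative slope. A slope can also pass where LPSp_40 alone differs, so these counts do not show a graded response to dose. The trend count was 14 without control replicate 5 and 790 without LPSp_20 replicate 7. It was 224, 77, 126 and 51 without control replicates 1, 3, 4 and 6, 53 without LPSp_20 replicate 6, and 26, 29, 18, 15 and 75 without LPSp_40 replicates 1, 2, 3, 6 and 7. Both doses shared 38 called probes against control, 23 higher and 15 lower, and since both use the same 7 control arrays, some sharing is built in. Among named genes ubiquitin-conjug 05024, uncoupling prote 05108 (0.62 ± 0.13 in LPSp_40, adjusted p = 0.0181) and histone h5a 02093 passed at both. The 2 other probes of histone h5a 02093 had the same sign and passed at neither dose. The 2 comparisons of LPSp_40 shared 440 probes, 430 higher and 10 lower, and both use the same 7 LPSp_40 arrays. Across probes, which are not independent replicates, the log2 changes of the 2 doses against control correlated with r = 0.543. Simulated groups without change, against shared controls, gave a median of 0.524, with 47 of 100 at least as high. With the controls split so that each dose had its own, the median r was 0.284 over 70 splits.

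Interferon and antiviral genes were also compared within positions of the arrays. Within row 1, the list mean of LPSp_40 exceeded control by 1.09 (exact permutation p = 0.00126, 5 against 7 arrays, the smallest that 792 splits can give). Within row 2 it exceeded LPSp_20 by 2.06 (exact permutation p = 0.0278, 2 against 7 arrays, the smallest that 36 splits can give). Within slide 1 it exceeded control by 1.57 (95% interval 1.27 to 1.87) and within slide 2 by 1.05 (-0.52 to 2.61). Slide 1 set LPSp_40 replicates 1, 2 and 3 against control replicates 1 and 2. Slide 2 set LPSp_40 replicates 4, 5 and 6 against control replicates 3 and 4, so both rest on few arrays. The first principal component held 35.6% of the variance, and diet was related to the fourth (5.86%, permutation adjusted p = 0.0222 over 12 tests). For the second component (14.1%), row had a permutation p = 0.00959 (adjusted 0.0575) and diet p = 0.0170 (adjusted 0.0680). With diet in the model, 0 probes passed for row (limma, 3388 at an unadjusted p under 0.05) and 28 for slide (4562). Row beside diet varies only inside LPSp_40 (2 arrays against 5), so this fit could hardly detect an effect of row.

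Lists of immune sensing and of other cell types gave no call in any of the 3 comparisons, quoted here in the order LPSp_20 against control, LPSp_40 against control and LPSp_40 against LPSp_20. LPS sensing and TLR-NFkB signalling had adjusted p = 0.732, 0.345 and 0.558, pro-inflammatory cytokines and chemokines 0.728, 0.774 and 0.553, and anti-inflammatory and regulatory genes 0.728, 0.619 and 0.368. Acute phase and antimicrobial genes had 0.488, 0.345 and 0.0881, lectins and scavenger receptors 0.993, 0.122 and 0.153, and MHC and antigen presentation 0.934, 0.400 and 0.553. T and NK cell markers had 0.934, 0.780 and 0.666, erythroid genes 0.239, 0.122 and 0.699, liver genes 0.150, 0.660 and 0.320, and muscle genes 0.239, 0.774 and 0.364. Proliferation genes had 0.455, 0.780 and 0.553, glycolysis and carbohydrate metabolism 0.740, 0.400 and 0.642, heat shock and ER chaperones 0.0738, 0.131 and 0.699, apoptosis 0.646, 0.345 and 0.699, and lysosome and autophagy 0.262, 0.345 and 0.777. Genes of these lists that rose in LPSp_40 against control included suppressor of cy 04511 (0.83 ± 0.20, adjusted p = 0.0394) and tpm1 protein 04713, of the muscle list (0.60 ± 0.13, adjusted p = 0.0224). The lipopolysacchari 02454 transcript was not well above background on any LPSp_40 array and was at least 5.08-fold higher in control, on 6 of 7 arrays, than its background floor in LPSp_40 (adjusted p = 0.137), and at least 2.88-fold without control replicate 6.

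Lists called in only part of the comparisons gave these values elsewhere. Against control in LPSp_40, complement had adjusted p = 0.169, ribosomal proteins 0.131, translation factors 0.619 and oxidative phosphorylation 0.122. Lipid metabolism had 0.345, oxidative stress 0.165, immediate early genes 0.122 and macrophage and granulocyte markers 0.0743, and cd68 antigen 00711 rose (0.89 ± 0.19, adjusted p = 0.0160). In LPSp_20 against control, macrophage markers had 0.993, oxidative phosphorylation 0.176, lipid metabolism 0.362, oxidative stress 0.489, immediate early genes 0.659, the proteasome list 0.488 and extracellular matrix 0.169. Between the doses, complement had 0.553, B cell genes 0.346, intestine and epithelium 0.268, the proteasome list 0.251 and extracellular matrix 0.251. In LPSp_20 against control, the median, mean and test direction differed in sign for LPS sensing, acute phase, lectins, T and NK cell markers, lipid metabolism and immediate early genes. They also differed for LPS sensing, anti-inflammatory, T and NK cell, liver and muscle lists in LPSp_40 against control, and for LPS sensing, anti-inflammatory, MHC, T and NK cell, erythroid, apoptosis and proteasome lists between the doses.

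Some lists without a call gained one by the preset correlation when 1 array was left out, and with all arrays and an estimated correlation the lists below had adjusted p = 0.674 to 0.892. In LPSp_20 against control these were muscle, lower (0.0440), and lysosome, higher (0.0192), without LPSp_20 replicate 7, and heat shock, higher, without control replicate 2 (0.0459). Oxidative phosphorylation was higher without control replicates 3 (0.00115) or 5 (0.0372) or LPSp_20 replicate 3 (0.0147). In LPSp_40 against control, macrophage markers were higher without control replicate 6 (0.0270) or LPSp_40 replicates 2 (0.0436) or 4 (0.0165), and erythroid genes without control replicate 3 (0.0196) or LPSp_40 replicate 3 (0.0133). Ribosomal proteins were lower without control replicate 6 (0.0450) or LPSp_40 replicates 1 (0.0437), 4 (0.0165) or 7 (0.0107). Oxidative phosphorylation was lower without control replicates 2 (0.0457) or 6 (0.0174) or LPSp_40 replicate 1 (0.0126), and oxidative stress without LPSp_40 replicate 2 (0.0178). Immediate early genes were higher without control replicates 6 (0.0438) or 7 (0.0498). Between the doses, acute phase genes were higher without LPSp_20 replicates 4 (0.0498) or 5 (0.0250) or LPSp_40 replicates 2 (0.0398) or 4 (0.0238), and B cell genes without LPSp_20 replicate 5 (0.00854).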

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

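The tests of slide, row, single arrays, cell types and scaling below were chosen after the results had been seen, and the splits of the arrays were planned before. For the interferon list, the margin asked of the lowest LPSp_40 array was raised after the first outcome had been seen. For the intestine and epithelium list, the test was changed from the adjusted p to the list mean after the first outcome had been seen. By the adjusted p, the LPSp_20 call ended both without control replicate 6 and under quantile scaling, which would have counted for both explanations there, and both measures are given.

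Interferon and antiviral genes were higher in LPSp_40 than in control. With slide and row as terms the list mean stayed 1.05 log2 higher (95% interval 0.52 to 1.57), and the highest median of the macrophage, T and NK cell and B cell lists was 0.10 (SD of the members 0.55) against 1.39 for the interferon list. These values argue against slide or row and more leukocytes of 1 of these types as the whole cause. Of the LPSp_40 arrays, 5 lay at 1.23 to 2.12, while replicates 4 and 5, at 0.38 and 0.53, lay above the highest control array (0.32) by less than the control SD of 0.25, so a response in part of the pools cannot be told apart from 1 in all of them. Replicate 4 had 61.9% of spots well above background and 87 outlier-marked spots, against 73.0% and 38 in replicate 5. Both lay in slide 2, row 1, and whether array quality or that position lowered their values was not tested. The tank of each pool is not given, so a difference between tanks, such as an infection in the tanks of 1 diet, was not tested and stays open, as does diet, and the p-values measure the spread between pools.

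The 226 probes called in LPSp_20 against control came from arrays that were all in row 2, against controls all in row 1. Inside LPSp_40, the row difference over these probes, signed by the call, had a median of 0.0574 log2 (2 arrays of row 2 against 5 of row 1, with 6 of the 21 ways to take 2 arrays as high), against a called change of 0.648. With a row term the median change was 0.624 and its median SE rose from 0.122 to 0.228, so that 0 probes passed in limma (3237 at an unadjusted p under 0.05). Both values rest on the same 2 against 5 LPSp_40 arrays, where the 21 ways gave medians of -0.125 to 0.125. They argue against the row as the whole cause only if it acted alike in all diets. An effect of row particular to the LPSp_20 or control arrays cannot be told apart from diet. The call itself was not held with the row term because the error grew. Without LPSp_20 replicate 7 the count was 471, with 57.5% higher in place of 38.5%. The count of LPSp_40 against control, which uses that array only through the spread that the model shares between diets, rose too, from 696 to 1003. A larger count therefore cannot show whether the 226 calls depend on replicate 7. Without LPSp_20 replicate 3 the count was 113, all among the 226. Without both it was 168, and without both and control replicate 6 it was 100. The part of single arrays stays open, as do diet and tank, which were not tested.

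Intestine and epithelium markers were lower in both LPSp diets than in control by the preset correlation, with adjusted p = 0.595 in LPSp_20 and 0.106 in LPSp_40 with an estimated correlation and 0.268 and 0.0816 in exact permutation tests of the list means, and the LPSp_20 call was lost with a row term (adjusted p = 0.972) and turned with the filter on all 21 arrays (0.619). In LPSp_20 the list mean was -0.92 (95% interval -1.71 to -0.13) and went to -0.64 (-1.31 to 0.04, adjusted p = 0.141) without control replicate 6, so whether 1 control pool rich in epithelial transcripts, with a list mean of 1.69, made this difference cannot be told apart from diet with so few pools. In LPSp_40 it was -1.22 and stayed at -0.94 (-1.62 to -0.27, adjusted p = 0.00469) without that pool, which argues against it as the whole cause there. The LPSp_40 call was lost, however, with the filter on all 21 arrays (camera adjusted p = 0.126), and the list mean includes values not well above background. At the background floor and without that pool, muc2 protein 02867 had -2.92, claudin 4 00908 -0.997 and mucin subtype tr 02871 -0.85 in LPSp_40 against control. Quantile scaling left -0.90 (-1.65 to -0.15, adjusted p = 0.0760) in LPSp_20 and -1.17 (-1.92 to -0.42, adjusted p = 0.000181) in LPSp_40, so the size of the difference argues against the scaling, although the LPSp_20 call was lost. In control replicate 6 the genes envoplakin 01436 (at least 7.34, well above background on 8 of 21 arrays), muc2 protein 02867 (7.32, on 16) and claudin 4 00908 (at least 6.59, on 10) lay that far, in log2, above the median of the other 20 arrays with values raised to the background floor, and effects of diet, row or tank stay open.

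Of 141 groups of 7 values examined, 18 had 1 array far from the other 6, where chance would mark about 1 in 20 independent groups, or 7.05. The groups share arrays and are not independent, so 18 cannot be weighed against that number. The lists examined were those called in a comparison and the liver list, which was called in none. The percentage of spots well above background was 69.1 in LPSp_20 replicate 7 against 72.8 to 75.03 in the other arrays of the diet, and 61.9 in LPSp_40 replicate 4 against 71.2 to 74.3. LPSp_40 replicate 4 also had 87 spots marked as outliers by the scanner software against 7 to 38. The mean correlation of LPSp_40 replicate 2 with the other arrays of its diet was 0.923 against 0.941 to 0.952.

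In LPSp_20 replicate 7 the list means in log2 lay far from those of the other 6 arrays for complement (1.38 against 0.14 to 0.38), proteasome and ubiquitin (-0.28 against 0.07 to 0.14) and extracellular matrix (-0.48 against -0.09 to 0.17). The same array stood apart for lipid metabolism (1.30 against -0.37 to 0.09), oxidative stress (0.71 against -0.33 to 0.10) and liver genes (2.56 against -0.14 to 0.11). LPSp_20 replicate 1 had an intestine and epithelium mean of 0.44 against -1.71 to -0.84. LPSp_40 replicate 6 had a lipid metabolism mean of -1.004 against -0.44 to -0.02.

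Among named genes, b cell rag assoc 00384 stood at 2.65 in control replicate 7 against 1.39 to 1.90, and at 1.79 in LPSp_40 replicate 1 against 2.47 to 2.83. Glutamine synthe 01788 stood at -3.18 in control replicate 1 against -2.36 to -1.94. In LPSp_20 replicate 4, nicotinamide pho 03079 stood at -2.36 against -5.52 to -4.31 and asparagine-linke 00334 at -2.56 against -2.46 to -2.40. Nuclear receptor 03245 stood at -4.59 in LPSp_20 replicate 7 against -2.64 to -1.82.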

How the results depend on the processing

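Leaving out the arrays that stood apart was chosen after seeing the data, and the other alternatives were chosen before. The counts of LPSp_40 against control and against LPSp_20 stayed within 1.5 times of 696 and 617 under every scaling, background correction and filter tried, while the count of LPSp_20 against control (226) and the trend (368) depended on more settings. Of the alternative values of counts, 85 moved by over 1.5 times and 221 did not. Of those of named genes, 629 kept direction and call, 60 lost a call, 21 gained one and 4 turned, and of those of lists 111 kept, 56 lost, 1 gained and 3 turned. The cause of these moves was not tested.

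Without a filter, 150 probes passed in LPSp_20 against control and 51 in the trend. With 1 probe per gene, which tests fewer probes by construction, the counts were 65 for LPSp_20 and 176 for LPSp_40 against control, 158 between the doses, 246 for any difference and 95 for the trend. With slide as a fixed block the trend had 24. Within slide 1 the counts were 0 (limma, 3379 at an unadjusted p under 0.05), 15, 192, 88 and 0 (4085) in that order, where 178 of the 192 were among the 617. Within slide 2 they were 0 (4365), 0 (6962), 0 (3926), 0 (5565) and 1.

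With a row term LPSp_20 against control had 0 (3237 unadjusted) and LPSp_40 against control 302, of which 291 were among the 696. With slide and row terms these were 0 (3704) and 241, of which 223 were shared, and any difference had 604. Among arrays of row 1 alone LPSp_40 against control had 4, and among arrays of row 2 alone LPSp_40 against LPSp_20 had 249, of which 207 were among the 617. With the replicate number as a block, although the labels give no such pairing, the counts were 73 for LPSp_20 against control and 37 for the trend. Array weights gave 1051 for LPSp_20 against control and 1584 for any difference, with the lowest weight for LPSp_20 replicate 7 (0.141). At an adjusted p under 0.10 the counts were 444 for LPSp_20, 1405 for any difference and 795 for the trend. At an unadjusted p under 0.01 with 1.5-fold they were 619, 1309, 938, 1448 and 1262. With the 2 compared groups alone, LPSp_20 against control had 83 and LPSp_40 against LPSp_20 had 395.

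Leaving out 1 array at a time gave 113 to 471 for LPSp_20 against control, 438 to 1003 for LPSp_40 against control, 471 to 700 between the doses, 693 to 1283 for any difference and 14 to 790 for the trend. Without LPSp_20 replicates 3 and 7 the trend had 815, and without these and control replicate 6 it had 704 and LPSp_20 against control 100. The correlation of the doses was 0.284 with split controls and 0.430 with the filter on all 21 arrays.

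The number of called lists in LPSp_20 against control, 5, was 0 with an estimated correlation, 1 with quantile scaling, 10 with a row term, 3 with the filter on all 21 arrays, 3 without the 3 arrays standing apart, and 3 to 7 without 1 array, with 3 each without control replicate 6, LPSp_20 replicate 4 or 5 or LPSp_40 replicate 7. In LPSp_40 against control, 5 became 1 with an estimated correlation, 3 with the filter on all 21 arrays, 8 without the 3 arrays, and 4 to 9 without 1 array, with 9 without control replicate 6. Between the doses, 8 became 1 with an estimated correlation, 2 with quantile scaling, 3 without the 3 arrays, and 3 to 9 without 1 array, with 3 without LPSp_40 replicate 5 and 4 without LPSp_20 replicate 7 or LPSp_40 replicate 6.

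Directions turned for ribosomal proteins with quantile scaling in LPSp_20 against control (adjusted p = 0.862) and between the doses (adjusted p = 0.118), and for intestine and epithelium in LPSp_20 with the filter on all 21 arrays (adjusted p = 0.619). The log2 change turned for complement compo 00991 (-0.24) and anterior gradien 00297 (0.039) in LPSp_20 with a row term, and for 60s acidic ribos 00049 (0.013) and elongation facto 01405 (0.043) between the doses with quantile scaling. No scaling moved the median of all probes by over 0.1.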

Other observations

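The families, single genes and arrays below were chosen after their values had been seen, and the splits of the arrays were planned. Further genes that rose in LPSp_40 against control were signal transduce 04311 (1.80 ± 0.33, adjusted p = 0.00532), pre-b cell enhan 03559 (1.77 ± 0.25, adjusted p = 0.00149) and cd9 antigen 00722, a tetraspanin (1.71 ± 0.34, adjusted p = 0.00850). Poly adp-ribose 03516 rose by 1.14 (adjusted p = 0.00560), ubiquitin-activa 05013 by 0.88 (adjusted p = 0.00879) and retinoid x beta 03966 by 0.93 (adjusted p = 0.0284). Of the 5 ubiquitin-like p identifiers, 3 rose in LPSp_40 against control (median log2 2.32) and 3 against LPSp_20 (median 2.74), and 0 passed in LPSp_20 against control in limma (median -0.03). Of the 12 fish virus induc identifiers, 7 rose against LPSp_20 (median 1.39). Of the 4 glutamine synthe identifiers, 3 rose in LPSp_20 and 0 in LPSp_40 (limma, medians 0.90 and 0.52), and 0 passed between the doses (median -0.34).

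For 2 of the arrays, examples of named genes far from the median of the other 20 are given, with each value raised to the background floor of its array. LPSp_20 replicate 7 was higher for fatty acid bindi 01588 by at least 9.73 on the log2 scale (well above background on 8 of 21 arrays), apolipoprotein c-i 00306, a lipoprotein component, by 9.22 and organic solute t 03302 by 7.55. LPSp_20 replicate 3 was lower than the median of the other arrays for triglyceride lipase (-8.99), and not well above background for the hormone somatostatin 04402 (-8.52 or further) and c-type natriuret 01060 (-7.06 or further).

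In random splits of the arrays, the counts of probes were not reached by another split, while the counts of lists often were. The splits treated the pools as exchangeable and did not keep rows apart. They therefore cannot address differences between tanks or rows. For LPSp_20 against control, 1 of 100 splits, the real one, called as many as 226 probes (highest other 5), for LPSp_40 against control 1 of 100 as many as 696 (highest other 10), and between the doses 1 of 100 as many as 617 (highest other 16). For any difference 1 of 100 regroupings called as many as 917 (highest other 3) and for the trend 1 of 100 as many as 368 (highest other 3). For lists called with the preset correlation, 57 of 100 splits called at least the 5 of LPSp_20 against control (highest other 11), 58 of 100 at least the 5 of LPSp_40 against control (highest other 13) and 31 of 100 at least the 8 between the doses (highest other 12).

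Arrays of the same replicate number had a median correlation of residuals of 0.02 between control and LPSp_20, against -0.03 for other numbers. It was 0.06 between control and LPSp_40 (against 0.03) and 0.15 between LPSp_20 and LPSp_40 (against -0.04). Of the 7 same-number pairs, 2, 2 and 5 exceeded 0.1 in that order. Whether the numbers pair the arrays was not tested. The median correlation between arrays within a diet was 0.959 in control, 0.932 in LPSp_20 and 0.952 in LPSp_40.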
